A study of Mus musculus with 6 samples.

How the data were processed

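Whole mouse kidneys at embryonic day 13.5 were profiled on Affymetrix MOE430.2 arrays, a 1-colour platform read from biotin-labelled cRNA made from 100 ng of total RNA. The labels give 2 genotypes with 3 biological replicates each. One carries wild-type Fz4 and no functional Fz8 (Fz8-null, replicates C1, C2 and C3) and the other lacks both receptors (double-null, replicates M1, M2 and M3). The mice were a hybrid of C57BL/6, 129X1/SvJ and 129S1/Sv. The labels do not state whether an array holds the kidneys of 1 embryo or of several, and they give no batch.

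The table deposited by the authors holds 1 log2 probe-set intensity per probe set and array, normalized between arrays with RMA by the authors (version not stated). Every array ran from about 2 to about 14 on this scale, with medians between 6.02 and 6.14, and the values were used as they were. Of the 45101 probe sets in the table, 64 Affymetrix control probe sets were set aside and 45037 were tested. The probe annotation gave exactly 1 gene for 34945 of these, several genes for 932 and none for 9160. Each of the 18193 genes was represented by the probe set with the highest mean over the 6 arrays among those that carry that gene alone. A position in the reference gene table (GRCm38.p6) was found for 18031 genes, and it was used only for distances from Fzd4 and Fzd8 and for counts per chromosome. Arrays carry no read depth, so the number of arrays limits the precision, and probe sets near a log2 value of 3 to 4 were read as near background.

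The double-null group was compared with the Fz8-null group by a linear model with moderated statistics (limma 3.58.1 under R 4.3.3, lmFit and eBayes without trend). Benjamini-Hochberg adjustment was done over the 45037 probe sets and, apart from that, over the 18193 genes, with a threshold of 0.05. Tests were two-sided, differences are double-null minus Fz8-null on the log2 scale, ± is the SD of 3 arrays, and SE is limma's moderated standard error. The probe sets of Fzd4 and Fzd8 were also compared by an exact permutation test, whose smallest possible p with 3 arrays against 3 is 0.1.

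The comparison, the tests, the gene lists and the rule for naming genes were set before the data were examined. There were 25 lists, which between them held 427 distinct genes, of which 395 were measured. Those of the kidney were ureteric tip, ureteric epithelium, nephron progenitors, committing nephron epithelium, podocyte and tubule, cortical and medullary stroma, and ureter mesenchyme and smooth muscle. Those of other cells that a dissected kidney can hold were endothelium, erythroid cells, macrophages and leukocytes, neurons and neural crest, gonad and mesonephric duct, adrenal cortex, liver, and skeletal muscle. Those of pathways were canonical Wnt targets, Wnt receptors and coreceptors, Wnt ligands and agonists, planar cell polarity, Ret-dependent transcripts, cell cycle, p53 and apoptosis, hypoxia and glycolysis, and immediate early genes. The sex-linked list was described per array and not tested. The other 24 lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Some genes stand in more than 1 list. For instance, all 11 measured Ret-dependent transcripts are in the ureteric tip list, the podocyte and tubule list shares 2 genes with the liver list, and the gonad list shares 3 with the adrenal list. Other genes, such as Lhx1, Sox9, Wnt4 and Wnt11, are shared between further lists.

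Named genes were Fzd4 and Fzd8, every gene past the threshold whose groups did not overlap (at most 12 in each direction), and from each list the members past the threshold or, where none passed, the 2 members of smallest p, given as values. Other list members named for their result adjusted over the list alone, and genes between adjusted p of 0.05 and 0.1, were chosen after their values were seen. Because fewer than 20 genes passed, the 200 genes of smallest p served for the test of genes near Fzd4, which compared genes within 10 Mb of Fzd4 with all other genes by Fisher's exact test, leaving out Fzd4.

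The alternatives set in advance were a minimum mean log2 value of 6, quantile normalization, equal array medians, eBayes with trend and robust settings, array weights, replicate number as a block, leaving out each array in turn, the mean of all probe sets of a gene, a 1.5-fold minimum, an adjusted p of 0.1, ordinary least squares without moderation, windows of 5 and 20 Mb, and leaving out genes within 10 Mb of Fzd4. Chosen after the data were seen were leaving out M1 and M2 together, covariates for the signal of the B1 repeat control and for the Y-linked level, leaving out genes within 25 Mb of Fzd4, the 200 genes of smallest p where 20 or more passed, and shortened versions of the podocyte and p53 lists. No pairing by replicate number was seen. Residuals of same-numbered arrays correlated at 0.19, -0.20 and 0.17, within the range of the other pairs (-0.29 to 0.27). With 3 arrays in each group this cannot exclude a pairing. The calls were tested on simulated data of the same size, with noise drawn for each gene on its own. Of 100 genes planted with a log2 change of 1, 37 were called, of 100 planted with a change of 2, 86 were called, and there were 7 false calls. The simulation held no variation shared by genes within an array, so it does not show how the calls behave where such variation is large. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.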

Results

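The series held 6 arrays of whole mouse kidney at E13.5, of which 3 were Fz8-null and 3 were double-null for Fz4 and Fz8. Fz4 and Fz8, encoded by Fzd4 and Fzd8, are Frizzled receptors for Wnt ligands. The comparison asked what loss of Fz4 changes in the kidney when Fz8 is already absent, as part of a question about the role of the receptor pair in growth of the ureteric tree.

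Fzd4 was far lower in the double-null kidneys: its representative probe set (1434756_at) read 10.84 ± 0.09 (SD, n = 3) in Fz8-null kidneys and 4.71 ± 0.74 (SD, n = 3) in double-null kidneys. The list means of the ureteric tip, where the collecting system branches, and of the nephron progenitors that surround it lay lower in all 3 double-null arrays, with 12 of 18 and 10 of 20 genes below every Fz8-null array in each of the 3. Both lists were called by camera at its preset correlation (adjusted p = 2.38e-06 for each), and neither was with an estimated one (adjusted p = 0.224 with an estimated correlation). Ret, the receptor tyrosine kinase that drives branching, stood at a log2 difference of -1.11 (SE 0.25), and Gdnf, which encodes its ligand and is made by the progenitors, at -0.73 (SE 0.16). Neither passed over all genes (limma adjusted p = 0.314 for Ret), and Gdnf was named after its value was seen. Whole kidneys were profiled, so a change in the share of a cell type cannot be told from a change within its cells. Liver transcripts such as Alb and Afp lay higher in double-null kidneys, most of all in M2 and M3. Several hybridization and ribosomal control probe sets also read higher in all 3 double-null arrays, and their bearing on these differences was not tested.

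Fzd4 fell by 6.13 on the log2 scale (SE 0.35, limma adjusted p = 0.00318). A less bright Fzd4 probe set (1419301_at) fell by 3.51 (SE 0.20, adjusted p = 0.00957), and a dim one (1449416_at) stood at -0.63 (SE 0.28, adjusted p = 0.327). The first 2 gave an exact permutation p of 0.1, the smallest possible, and the dim one gave an exact p of 0.2. In M1, M2 and M3 the brightest Fzd4 probe set read 5.29, 4.96 and 3.89, and the lowest Fz8-null array read 10.74; the double-null values approach the background of the arrays, which bounds the measured difference. Leaving out C1 or C3 put the adjusted p of Fzd4 at 0.0635 or 0.0507 with differences of -6.18 and -6.09. Fzd8 read 3.98 ± 0.42 in Fz8-null and 3.69 ± 0.18 in double-null kidneys (SD, n = 3 in each; probe set 1423348_at), a difference of -0.29 (SE 0.23, adjusted p = 0.529; exact permutation p = 0.3). This difference was -0.48 without C1 and -0.065 without C2, and with array weights it passed (-0.56, adjusted p = 0.0339). A further Fzd8 probe set (1445815_at) stood at 0.034 (exact permutation p = 0.8), and both lay near the background of the arrays.

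Besides Fzd4, 4 genes passed the threshold. Trim12a, a member of the tripartite motif family, fell by 3.31 (SE 0.13, adjusted p = 0.000688; 1437432_a_at), from 6.57 ± 0.11 to 3.26 ± 0.08 (SD, n = 3 in each), a level near background that bounds the measured fall. Ctr9, a subunit of the PAF1 complex that acts in transcription elongation, fell by 4.10 (SE 0.19, adjusted p = 0.00141; 1422679_s_at), from 11.31 ± 0.22 to 7.21 ± 0.28 (SD, n = 3). Vsnl1, which encodes a neuronal calcium sensor also made in the ureteric tip, fell by 1.90 (SE 0.17, adjusted p = 0.0490; 1450055_at), from 6.64 ± 0.11 to 4.73 ± 0.28 (SD, n = 3). Hddc3, a pyrophosphohydrolase, rose by 2.09 (SE 0.18, adjusted p = 0.0350; 1428692_at), from 8.20 ± 0.19 to 10.29 ± 0.24 (SD, n = 3). Probe sets of the same gene differed for 3 of them: the other Ctr9 probe sets stood between -0.53 and -0.22, that of Trim12a at 0.32 and that of Hddc3 at -0.18, and that of Vsnl1 stood at -1.70. With the mean of all probe sets of a gene only Fzd4 passed.

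**Figure D1:**
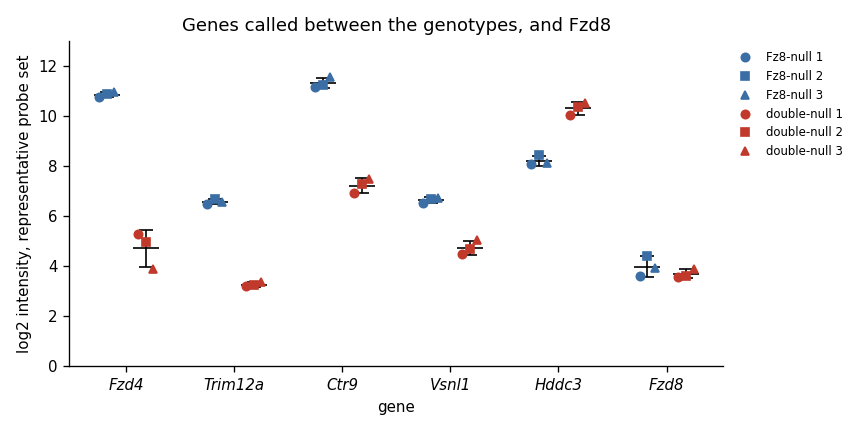
Log2 intensity of the representative probe set (vertical axis) of the 5 genes past the threshold and of Fzd8 in each of the 6 arrays, with the group mean and SD (n = 3). The groups of each of the 5 genes do not overlap, and both groups of Fzd8 lie below 4.5.

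In all, 5 of 18193 genes passed (1 higher, 4 lower) and 5 of 45037 probe sets (0 higher, 5 lower; 2 of Fzd4, 1 each of Trim12a and Ctr9, and 1444252_at, which has no gene name, at -3.12). The double-null mean of 1444252_at was 3.37, a level near background that bounds its measured fall. At an unadjusted p under 0.05 limma gave 3043 probe sets higher and 3913 lower, and 1101 genes higher and 1679 lower. The groups did not overlap for 3435 genes, which is 18.9%, where chance gives 10% on average over all splits of the arrays. Genes vary together within an array, so a single split can depart from that average, and the share in other splits was not counted. Of the 3435 genes, 2219 were lower and 1216 higher in double-null kidneys. The median difference was -0.061 over all genes and -0.15 over the genes with a mean of at least 6, so brighter genes lay lower in general. Between an adjusted p of 0.05 and 0.1 stood Prkag3 at -1.39, Ppme1 at -1.80, Trim6 at -1.55 and Myo7a at -1.54, and on the higher side Bhmt, a liver and kidney enzyme of methionine metabolism, at 3.23 and Agmat at 1.10. The number of genes passing depended on single arrays: 3292 passed without M3 (1346 higher, 1946 lower), 39 without M1 (35 higher, 4 lower), 4 without M2, 3 without C1, 3 without C2 and 2 without C3. Hddc3 and Vsnl1 did not pass without C1, C2, C3 or M2, with adjusted p from 0.138 to 0.424 for Hddc3 and from 0.138 to 0.479 for Vsnl1. Neither passed with the replicate block (adjusted p = 0.133 for each) or with the B1 or the Y-linked covariate (adjusted p = 0.0886 and 0.0956 for Hddc3, 0.188 and 0.112 for Vsnl1), nor did Vsnl1 with quantile normalization (0.0811) or eBayes with trend and robust settings (0.0581). In these fits the differences stayed between 2.02 and 2.30 for Hddc3 and between -1.96 and -1.60 for Vsnl1.

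The ureteric tip list was lower in double-null kidneys. Of its 18 measured genes 17 lay lower, 12 of them with all 3 double-null arrays below every Fz8-null array, and the mean difference was -0.62 (camera adjusted p = 2.38e-06; adjusted p = 0.224 with an estimated correlation; fry adjusted p = 0.0226). Over all genes 1 member fell (Vsnl1), and adjusted over the list alone 9 fell. These included Slco4c1, an organic anion transporter, at -1.33, Sox8 at -1.21, Ret at -1.11, its coreceptor gene Gfra1 at -0.89 and Etv5, a transcription factor gene downstream of Ret, at -0.74. Sox9, which is redundant with Sox8 in branching, stood at 0.06, and Wnt11, a tip ligand gene, at -0.21. The list mean was -0.58 in M1, -0.79 in M2 and -0.48 in M3, against the mean of the Fz8-null arrays, and -0.46 with the B1 repeat signal as a covariate.

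All 11 measured Ret-dependent transcripts, each of them also in the tip list, lay lower, with a mean of -0.48 (camera adjusted p = 0.000975; adjusted p = 0.224 with an estimated correlation; fry adjusted p = 0.0508). None fell over all genes, and 4 fell when adjusted over the list alone. The mean was -0.44 in M1, -0.69 in M2 and -0.31 in M3, and -0.30 with the B1 repeat signal as a covariate (camera adjusted p = 0.000454). The 4 genes were Ret, Etv5, Mmp14, a membrane-anchored metalloproteinase gene, at -0.99, and Etv4 at -0.82. Arrays of whole kidney cannot tell a smaller share of tip cells from lower transcript levels within them. The ureteric epithelium list gave no call, with 13 of 23 genes lower and a mean of -0.16 (camera adjusted p = 0.403; 0 genes fell over all genes and 0 adjusted over the list alone). Its genes of smallest p were Elf3 at -0.69 and Gata3, a transcription factor gene of the nephric duct, at -0.38. The mean of this list was -0.15 in M1, -0.46 in M2 and 0.13 in M3, and it was -0.012 without M2 and -0.30 without M3.

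Nephron progenitor genes were lower as well. Of 20 measured genes 19 lay lower, 10 of them without overlap, and the mean was -0.51 (camera adjusted p = 2.38e-06; adjusted p = 0.224 with an estimated correlation; fry adjusted p = 0.0226). None fell over all genes, and 6 fell when adjusted over the list alone: Osr1 at -1.26, Crym at -1.24, Cited1 at -1.02, Meox1 at -0.81, Traf1 at -0.78 and Gdnf at -0.73. Osr1 and Cited1 are transcriptional regulators that mark the early and uncommitted progenitor. The shift was -0.56 in M1, -0.63 in M2 and -0.34 in M3, so it was larger in the arrays with the highest B1 repeat signal, and it was -0.35 with that signal as a covariate. The list of the committing nephron epithelium gave no call, with 15 of 24 genes lower and a mean of -0.11 (camera adjusted p = 0.445; 0 passed over all genes and 0 adjusted over the list alone). Fgf8 stood at -0.92 and Irx2 at 0.73. The committing nephron mean was -0.093 in M1, -0.26 in M2 and 0.030 in M3, and it was -0.032 without M2 and -0.18 without M3.

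Podocyte and tubule genes were higher as a group, 15 of 19 measured, with a mean of 0.50 (camera adjusted p = 0.00151; adjusted p = 0.559 with an estimated correlation; fry adjusted p = 0.274). None passed over all genes or adjusted over the list alone. Clic5, a podocyte gene, stood at 0.73, and Ttr, which is also in the liver list, at 3.65. Without the 2 genes shared with the liver list the mean of the other 17 was 0.28 (camera adjusted p = 0.0105). Cortical and medullary stroma had a mean of 0.011 (camera adjusted p = 0.424), with 12 of 23 genes higher and 11 lower. There 0 genes passed over all genes, and 1 fell when adjusted over the list alone. That gene was Ntrk3, a neurotrophin receptor gene 11.0 Mb from Fzd4, at -1.90, and its probe sets ranged from -2.47 to 0.45. Dcn, a matrix proteoglycan gene, stood at 0.60. The stroma list was called higher without M2 (0.13, camera adjusted p = 0.0271), with a minimum mean of 6, without M1 and M2 together, and with the B1 covariate. Ureter mesenchyme and smooth muscle gave no call (19 genes, mean 0.018, median -0.0099, camera adjusted p = 0.545; 0 over all genes and 0 adjusted over the list alone), with Myocd, a smooth muscle regulator, at 1.19 and Aldh1a1 at -0.71.

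**Figure D2:**
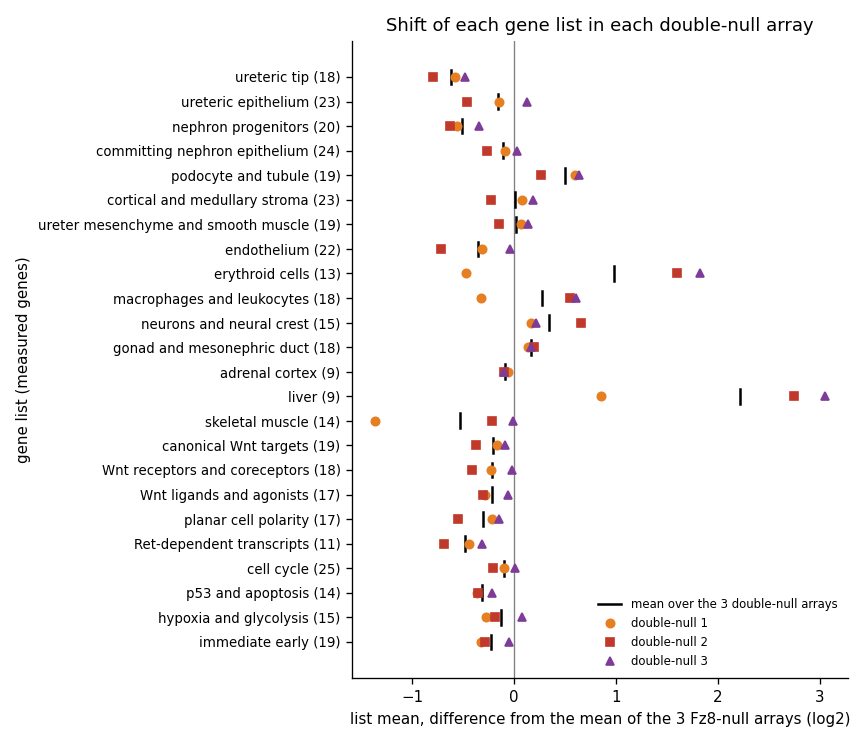
Mean log2 difference of each gene list from the mean of the 3 Fz8-null arrays (horizontal axis), for each double-null array and as the mean of the 3, with the number of measured genes in brackets. Ureteric tip and nephron progenitors lie below 0 in all 3 arrays; liver lies above 0 in all 3, and erythroid cells lie above 0 in M2 and M3 and below 0 in M1.

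Liver transcripts had the largest mean difference of the 24 lists tested. All 9 measured genes lay higher, 6 of them without overlap, with a mean of 2.22 (camera adjusted p = 3.23e-07; adjusted p = 0.224 with an estimated correlation; fry adjusted p = 0.0963). None rose over all genes, and 8 rose when adjusted over the list alone, among them Ttr at 3.65, Alb, the albumin gene, at 3.63, Afp, the fetal serum protein alpha-fetoprotein, at 3.22 and Apoa1 at 2.74. The list mean was 0.85 above the Fz8-null mean in M1, 2.75 in M2 and 3.05 in M3, and with array weights the mean was 1.04 (camera adjusted p = 0.0106). Erythroid genes followed M2 and M3 too, with 11 of 13 higher and a mean of 0.98 (camera adjusted p = 0.00158; adjusted p = 0.660 with an estimated correlation; fry adjusted p = 0.433; 0 over all genes and 0 adjusted over the list alone). Hemgn, a regulator gene of blood progenitors, stood at 3.06 and Rhag, an erythrocyte membrane protein gene, at 1.09. Rhag lay near background, with a mean of 2.85 in Fz8-null and 3.95 in double-null kidneys. The estimated correlation was 0.67 for the erythroid list and 0.31 for the liver list, against the preset 0.01. The erythroid mean was -0.47 in M1, 1.60 in M2 and 1.82 in M3. It was 1.71 without M1 and 0.56 without M3, and the call ended without M3 (camera adjusted p = 0.162).

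Macrophage and leukocyte genes were higher, 14 of 18, with a mean of 0.28 (camera adjusted p = 0.0209; adjusted p = 0.660 with an estimated correlation; fry adjusted p = 0.563; 0 over all genes and 0 adjusted over the list alone). C1qb, a complement gene of macrophages, stood at 1.27 and Lyz2 at 1.36, and the list mean was -0.33 in M1, 0.54 in M2 and 0.61 in M3. Without M1 the list mean was 0.58, and the call ended without C1, M2 or M3 (0.21, 0.14 and 0.11; camera adjusted p = 0.212, 0.122 and 0.431). With array weights the means of the erythroid and macrophage lists turned to -0.19 and -0.26. Neuron and neural crest genes were higher, 13 of 15, with a mean of 0.35 (camera adjusted p = 0.00200; adjusted p = 0.559 with an estimated correlation; fry adjusted p = 0.274; 0 over all genes and 0 adjusted over the list alone). Sox10, a glial and crest regulator, stood at 0.44 and Chga, which encodes a granule protein of chromaffin cells, at 0.53. The neuron list mean was 0.17 in M1, 0.66 in M2 and 0.21 in M3, and it was 0.19 without M2. It was not called with array weights (0.25, adjusted p = 0.136) or with the B1 repeat signal as a covariate (0.15, adjusted p = 0.253).

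Endothelial genes were lower, 18 of 22, with a mean of -0.36 (camera adjusted p = 0.00551; adjusted p = 0.660 with an estimated correlation; fry adjusted p = 0.318; 0 over all genes and 0 adjusted over the list alone). Kdr, the main VEGF receptor gene, stood at -0.80 and Esam, a junction protein gene, at -0.61. The endothelial shift was -0.32 in M1, -0.71 in M2 and -0.043 in M3, so it followed the arrays with the highest B1 repeat signal. The mean was -0.18 without M2 and -0.043 without M1 and M2 together (camera adjusted p = 0.396), and -0.0042 with the B1 signal as a covariate (camera adjusted p = 0.905). With a minimum mean of 6 the list was not called (camera adjusted p = 0.103). Gonad and mesonephric duct (18 genes, mean 0.16, camera adjusted p = 0.230), adrenal cortex (9 genes, mean -0.087, median 0.0052, camera direction up, camera adjusted p = 0.793) and skeletal muscle (14 genes, mean -0.53, camera adjusted p = 0.219) gave no call, and 0 of their genes passed over all genes or adjusted over the list alone. Their genes of smallest p were Dazl, a germ cell gene, at 1.74, Star, a cholesterol carrier gene of steroid cells, at -0.75, Mc2r, the ACTH receptor gene, at -0.58, Myh3 at -1.29 and Chrna1 at -0.76. The adrenal mean was -0.13 without C1 and -0.045 without C2. Skeletal muscle lay at -1.37 in M1, -0.22 in M2 and -0.0077 in M3, and its mean was -0.083 without C2 and -0.11 without M1. Its list was called lower without C1 (-0.88, camera adjusted p = 0.0159) or M2 (-0.69, camera adjusted p = 0.0389), with array weights (-1.53, camera adjusted p = 0.0106) and with the replicate block (camera adjusted p = 0.0331).

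Among Wnt pathway lists, planar cell polarity genes were lower, 16 of 17, with a mean of -0.31 (camera adjusted p = 0.0119; adjusted p = 0.660 with an estimated correlation; fry adjusted p = 0.264). Fjx1 stood at -0.47 and Dvl2, a Dishevelled gene, at -0.68. Genes of Wnt receptors and coreceptors other than Fzd4 and Fzd8 were lower, 16 of 18, with a mean of -0.22 (camera adjusted p = 0.0377; adjusted p = 0.660 with an estimated correlation; fry adjusted p = 0.274). Ryk, a Wnt receptor gene, stood at -0.30 and Tspan12, whose product works with Fz4, at -0.34. In neither list did a gene pass over all genes or adjusted over the list alone. The median over the genes with a mean of at least 6 was -0.15, against which such small list means are to be read. The planar cell polarity mean was -0.22 in M1, -0.55 in M2 and -0.15 in M3. The receptor mean was -0.22 in M1, -0.42 in M2 and -0.016 in M3. The planar cell polarity mean was -0.18 without M2, and its call ended without M3 (-0.38, camera adjusted p = 0.0677), with a minimum mean of 6, quantile normalization, array weights or the B1 covariate (-0.13, camera adjusted p = 0.102). The receptor call ended without C1 (-0.21, camera adjusted p = 0.0693), C3 (-0.22, camera adjusted p = 0.0651) or M2 (-0.12, camera adjusted p = 0.182) and with 7 other alternatives of the fit. The receptor mean was -0.012 with the B1 covariate (camera adjusted p = 0.905) and -0.016 without M1 and M2 (camera adjusted p = 0.736), so like the endothelial shift it followed the arrays with the highest B1 signal.

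Canonical Wnt targets gave no call, with 14 of 19 genes lower and a mean of -0.21 (camera adjusted p = 0.127; 0 over all genes and 0 adjusted over the list alone). Axin2, a feedback target of beta-catenin signalling, read 9.60 ± 0.05 in Fz8-null and 8.76 ± 0.40 in double-null kidneys (SD, n = 3 in each), a difference of -0.84 (SE 0.21, limma adjusted p = 0.314), and Notum, which encodes a Wnt-inactivating enzyme, stood at -0.74. The target mean was -0.17 in M1, -0.37 in M2 and -0.086 in M3, -0.13 without M2 and -0.085 with the B1 covariate. Wnt ligands and agonists gave no call (17 genes, mean -0.22, camera adjusted p = 0.228; 0 over all genes and 0 adjusted over the list alone), with Wnt6 at -1.003 and Wnt3 at -0.55, and a mean of -0.064 with the B1 covariate. Wnt3 lay near background, with a mean of 3.59 in Fz8-null and 3.04 in double-null kidneys. The p53 and apoptosis list was lower, 10 of 14, with a mean of -0.31 (camera adjusted p = 0.0377; adjusted p = 0.626 with an estimated correlation; fry adjusted p = 0.1797). It had 0 genes past the threshold over all genes, and 1 fell when adjusted over the list alone. That gene was Aen, a p53-induced nuclease gene 10.5 Mb from Fzd4, at -1.06, and Bcl2l11, a pro-apoptotic gene, stood at -0.53. Without Aen the mean was -0.26 and the call ended (camera adjusted p = 0.127). It also ended without C3 (-0.26, camera adjusted p = 0.107), M1 (-0.29, camera adjusted p = 0.0722) or M3 (-0.36, camera adjusted p = 0.118), and with 8 other alternatives of the fit.

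Cell cycle genes (25 measured, 17 lower, mean -0.098, camera adjusted p = 0.511), hypoxia and glycolysis genes (15 measured, 11 lower, mean -0.13, camera adjusted p = 0.424) and immediate early genes (19 measured, 14 lower, mean -0.22, camera adjusted p = 0.108) gave no call, and 0 of their genes passed over all genes or adjusted over the list alone. The mitotic kinase gene Aurkb stood at -0.41 and Foxm1 at -0.37, the glycolytic gene Hk2 at -0.84, Bnip3 at 0.38 and the stimulus-response gene Egr1 at -0.88. Ccn1 stood at -0.57 on its representative probe set, and others of its probe sets at 1.71 and 1.81. Immediate early genes were called lower without C1 (-0.31, camera adjusted p = 0.0141) and with array weights (-0.38, camera adjusted p = 0.0350), and their mean was -0.014 with the B1 covariate. The cell cycle mean was -0.042 without M2 and -0.15 without M3, and the hypoxia mean was -0.056 without M1 and -0.23 without M3.

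Genes close to Fzd4 were over-represented among those of smallest p. Within 10 Mb of Fzd4, 8 of 128 genes (6.25%) were among the 200 genes of smallest p, against 192 of 17902 elsewhere (1.07%), an odds ratio of 6.15 (95% interval 2.56 to 12.7, Fisher's exact test, p = 9.14e-05). Of the 5 genes past the threshold 4 lie on chromosome 7: Fzd4, Hddc3 at 9.06 Mb from it, Trim12a at 14.9 Mb and Ctr9 at 21.6 Mb. So do Myo7a at 8.68 Mb, Ppme1 at 10.9 Mb and Trim6 at 14.8 Mb. The share was 5.88% up to 5 Mb, 6.38% from 5 to 10 Mb, 4.29% from 10 to 20 Mb and 1.74% from 20 to 30 Mb, and 1.05% on other chromosomes. With the 200 genes of smallest p the odds ratio was 3.69 without C1, 3.69 without C3, 2.91 without M1 (exact p = 0.0543) and 2.16 without M3 (exact p = 0.170). Without genes within 25 Mb of Fzd4, but with Fzd4 itself kept, 1 gene passed the threshold. That gene was Fzd4, and Vsnl1 did not pass.

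**Figure D3:**
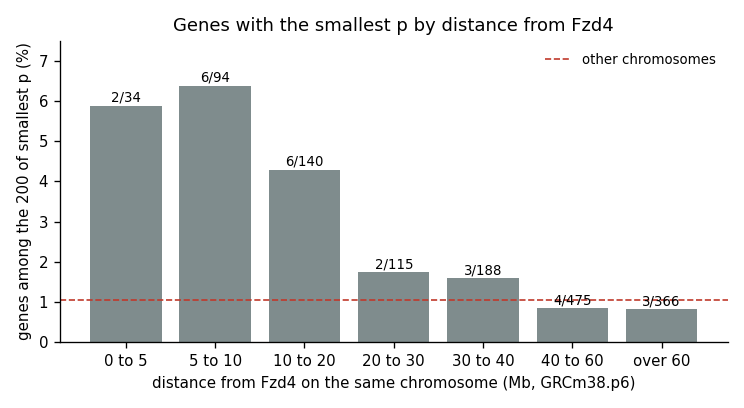
Percent of genes among the 200 of smallest p (vertical axis, from 0) by distance from Fzd4 on the same chromosome (horizontal axis, Mb, GRCm38.p6), with counts above the bars and the 1.05% of other chromosomes as a dashed line. The bars up to 20 Mb stand between 4.29% and 6.38%, and those beyond 40 Mb stand below the line.

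The 6 arrays did not separate by genotype alone. M1 and M2 lay apart from the other 4 arrays on the principal component that held 70.6% of the variance, at 84.0 and 115, while M3 lay at -41.7 and the Fz8-null arrays between -65.5 and -26.7. M3 correlated with the Fz8-null arrays at 0.987 to 0.990 across probe sets, and with M1 and M2 at 0.963 and 0.952; probe sets are not independent replicates. The control probe set for the B1 repeat, an element that lies in introns and untranslated sequence, read 11.83 in M1 and 12.08 in M2, 10.85 in M3 and 10.67 to 11.02 in the Fz8-null arrays. Leaving out M1 and M2 together leaves M3 as the only double-null array, so that the spread comes from the Fz8-null arrays alone and M3 is assumed to vary as they do. In that fit 55 genes passed (50 higher), all 5 of the reported genes among them, and the list means, which are those of M3, were -0.48 for the tip, -0.34 for progenitors, -0.31 for Ret-dependent transcripts and 3.05 for liver.

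**Figure D4:**
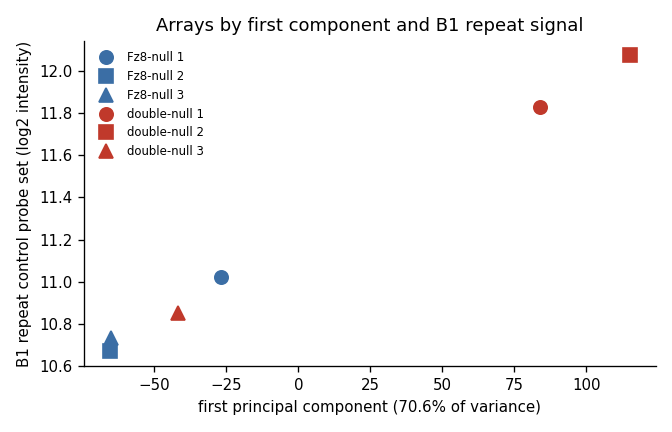
Signal of the B1 repeat control probe set (vertical axis, log2 intensity) against the score on the principal component that holds 70.6% of the variance (horizontal axis), for each of the 6 arrays. M1 and M2 stand at the upper right, and M3 stands among the Fz8-null arrays.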

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

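The tests of a wrong label of M3, of sex and of the liver change in every double-null sample, and that of Ctr9 and of genes left without a further probe set, were chosen only after the result was seen.

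Of the hybridization and ribosomal control probe sets, which stand outside the comparison of genes, 12 read higher in all 3 double-null arrays than in every Fz8-null array by over 0.5 on the log2 scale, while those of BioD differed by 0.15 to 0.39 and 3 of the 4 overlapped. The 3' and 5' probe sets of 18S ribosomal RNA differed by 1.73 and 2.11 on the log2 scale, while the middle 18S probe set differed by -0.09. The BioB probe sets, which detect a bacterial transcript spiked into the hybridization, differed by 0.73 (3'), 0.81 (5') and 0.76 (middle), and the BioC probe sets by 0.75 (3') and 0.72 (5'). Their r2 versions differed by 0.74 (bioB 3'), 0.74 (bioB 5'), 0.86 (bioB middle), 0.70 (bioC 3') and 0.68 (bioC 5'). C1 lay between C2 and C3 and the double-null arrays in all 12 of these, for instance at 10.05 on BioB 5' where C2 read 9.39, C3 9.29 and the lowest double-null array 10.22. These differences ran along with genotype, and their bearing on the gene and list differences was not tested.

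Genes near Fzd4 were over-represented among those of smallest p, with an odds ratio of 6.15, and the strain origin of the DNA linked to the targeted locus is a candidate explanation, which a low odds ratio would have argued against. The alternative that a sequence variant under the probes lowers single probe sets is argued against for Prc1, Homer2, Ntrk3 and Aen, whose 7 other bright probe sets moved by a median of 0.563 of the representative (quartiles 0.540 and 1.24), 6 of them in the same direction. It remains open for the other 10 of the 14 genes within 20 Mb, which have no other bright probe set. For Ctr9, just outside the window of 20 Mb, the other bright probe sets moved by a median of 0.110 of the representative. A variant under the probes of 1 probe set could give this. An effect of Fz4 loss on genes that happen to lie there was not tested and stays open.

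M1 and M2 stood apart from M3 and the Fz8-null arrays. Sex of the embryos is argued against, since Xist was 3.86 higher in M2 than in M1, and so is a wrong genotype label of M3, whose Fzd4 value differed by -6.86 from the lowest Fz8-null array. Differences in RNA quality or in unspliced and repeat-containing RNA may explain it: probe sets with no gene name were 0.268 higher than named ones of equal mean level in M1 and M2 against the other 4 arrays, in 48 of 50 level bins. The 3' minus 5' differences of the actin and Gapdh controls were highest in M1 (1.30 and 1.15) and M2 (1.08 and 1.04). C1 came close to M2 (1.00 and 1.01) without standing apart, so these controls do not decide on RNA quality. A difference between the embryos in stage or in severity of the phenotype was not tested and stays open.

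Liver transcripts were high in M2 and M3, where Alb read 10.82 and 11.03 and Afp 11.18 and 11.19, against Fz8-null means of 6.26 and 7.06. A change of the same size in every double-null sample is argued against by a further list of 20 liver transcripts, with median shifts of 0.085 in M1, 2.00 in M2 and 2.34 in M3; in the main list, on which the pattern was seen, M1 lay 1.90 below the lower of M2 and M3. Liver tissue or its cells in these samples could explain it: in the further list 13 of 19 measured genes (68.4%) lay at least 1 log2 unit above every Fz8-null array in both M2 and M3. This share lay between the limits set for and against that source, so the source stays open. The erythroid and macrophage lists were likewise higher in M2 (1.60 and 0.54) and M3 (1.82 and 0.61) but not in M1 (-0.47 and -0.33). The podocyte and tubule list, which shares 2 genes with the main liver list, did not follow this pattern (0.60 in M1, 0.27 in M2 and 0.64 in M3). Induction of these genes in part of the double-null kidneys was not tested.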

How the results depend on the processing

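Leaving out M1 and M2 together, the covariates, the 25 Mb exclusion and the use of 200 genes where 20 or more passed were chosen only after the data were seen. Among the limma fits with moderated statistics in which they were tested, Ctr9 and Trim12a passed in all except that of the mean of all probe sets of a gene, and Fzd4 in all except those without C1 or C3, with differences from -6.42 to -5.71 over the 6 omissions. Against 5 probe sets, 2 passed with a minimum mean of 6, 20686 with array weights, 0 with the replicate block, 36 without M1 and M2 (M3 alone, assumed to vary like the Fz8-null arrays), 1 with the Y-linked covariate, 0 by ordinary least squares (which called 1 gene, and 1839 at an unadjusted p under 0.05), and 0 to 10747 without single arrays. Against 5 genes, 7727 passed with array weights, 3 with the replicate block, 55 without M1 and M2, 3 with the B1 covariate, 3 with the Y-linked covariate, 1 with the mean of all probe sets, 11 at an adjusted p under 0.1, 3 without genes within 10 Mb of Fzd4, 1 without those within 25 Mb, and 2 to 3292 without single arrays. Array weights and leaving out M3 changed the counts most, and the thresholds and exclusions change by construction what is counted. For the others, array weights and M3 included, the cause was not tested. Without M3 the double-null group is M1 and M2 alone, which stand apart from the other arrays. The count without M3 therefore cannot be read as an effect of genotype alone. Of 12 lists called, 0 were with an estimated correlation and 2 with fry. The estimated correlations of the 12 lists ran from 0.066 (Ret-dependent transcripts) to 0.67 (erythroid cells), all above the preset 0.01. If these estimates hold, the p-values at the preset correlation are too small. Near Fzd4 the odds ratio was 5.62 within 5 Mb, 0.958 with array weights, 3.69 with equal array medians, the replicate block, the B1 covariate or the mean of all probe sets, 1.05 to 4.49 without single arrays, and 2.65 without M1 and M2; with 200 genes it was 3.69 with array weights, 2.91 without M1, 2.16 without M3 and 2.91 without M1 and M2. Fzd8 stood at -0.56 with array weights (adjusted p = 0.0339) and at 0.030 with the B1 covariate, and Ccn1 at 0.60 with the mean of its probe sets; the cause was not tested. Several list means changed sign, none of them to a called list. Without M1 and M2 and with the B1 covariate these were ureteric epithelium at 0.13 and 0.14, committing nephron at 0.030 and 0.029, cell cycle at 0.013 and 0.011, and hypoxia at 0.075 and 0.081. Skeletal muscle stood at 0.066 with the B1 covariate, erythroid cells at -0.19 and macrophages at -0.26 with array weights, and gonad at -0.43 with a minimum mean of 6. Smooth muscle stood at -0.036 with a minimum mean of 6 and -0.042 with the mean of all probe sets, and ranged from -0.042 to 0.10 without single arrays, and stroma from -0.077 to 0.13. The cause of these changes of sign was not tested. Of the values of named genes other than Fzd4 and Fzd8 and of lists under the alternatives, 1069 kept direction and side of the threshold, 77 no longer passed, 83 passed only there and 22 changed sign. Probe sets of low signal, among them those of Fzd8, Wnt3, Rhag and Chrna1, limit what can be read from small differences.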

Other observations

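The tests by chromosome and by distance from Fzd8 were chosen only after the result was seen.

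The genes of smallest p were also concentrated on chromosome 18, which carries Fzd8: 13 of its 459 genes were among the 200 of smallest p (2.83%; Fisher's exact test, adjusted over the chromosomes, p = 0.0379), with 4 of 59 within 10 Mb of Fzd8 and 9 of 400 beyond. A window of 30 Mb held 6 of 219, against 7 of 240 beyond it, so at that scale the share did not rise towards Fzd8. Both groups lack functional Fz8. Among the 13 genes were Spry4, a feedback inhibitor gene of receptor tyrosine kinase signalling, at -0.83 (29.4 Mb from Fzd8), the guidance gene Sema6a at -1.004 (38.1 Mb) and Aqp4, a water channel gene, at 1.27 (6.19 Mb), none of which passed over all genes. Chromosome 7 as a whole, where Fzd4 lies, held 26 of 1413 (adjusted p = 0.111).

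The arrays differed in their sex-linked transcripts within each genotype, and the list, of which 4 genes were measured, was not tested. Xist read 8.37 in M1 and between 10.90 and 12.23 in the other 5 arrays. The Y-linked gene Eif2s3y read 2.84 in C1, 5.50 in M2 and between 9.02 and 11.09 in the others. C2, C3 and M3 thus carried both Xist and Eif2s3y at high levels. Kdm5d, also Y-linked, read 7.72, 7.06 and 6.27 in these arrays, against 4.01 in C1 and 3.10 in M2. Together these values argue against the kidneys of a single embryo in each of C2, C3 and M3.

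The split of the 6 arrays by genotype gave 5 probe sets and 5 genes past the threshold, and the highest of the other splits gave 0, so 1 of 10 splits gave as many probe sets and 1 of 10 as many genes. With 10 splits a share under 0.05 cannot be reached.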
